A study of Mus musculus with 2 samples.

How the data were processed

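Live CD45+ cells, that is, cells carrying the surface protein shared by leukocytes, were measured by droplet single-cell RNA sequencing from dorsal skin of house dust mite-treated mice. There were 2 libraries, 1 from wild-type (WT) C57Bl/6 mice and 1 from mice lacking the IL-31 receptor alpha chain (IL31RAKO), each from 4 mice whose tissue was pooled before sorting. Per the labels' protocols, the libraries were made with version 2 of the 10x Single Cell 3′ kit from 30000 loaded cells each and read with 26 cycles for the barcode read and 98 cycles for the transcript read. Cell Ranger 3.1, Seurat 3.2.2 and the mouse build mm10 were used per the submitters' processing notes, which give no role for either tool. The deposited values were raw UMI counts (unique molecular identifiers, each standing for 1 captured RNA molecule) per gene and barcode, with no normalisation. The deposited matrices listed 737280 barcodes and 27998 genes each, empty droplets included, so that no cell filter of the authors had been applied to them. No annotation of cells was used, and the cells were called and named anew, so names may differ from those of the study.

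The WT library held 57000499 UMIs and the IL31RAKO library 71333292. Barcodes were kept as cells at 500 or more UMIs and 250 or more genes (13802 WT and 16169 IL31RAKO barcodes), with under 10% of UMIs from mitochondrial genes (11934 and 14619 left). Doublets, droplets holding more than 1 cell, were scored with Scrublet as built into scanpy, at an expected rate of 8%, and the top-scoring 0.8% per 1000 cells were removed, which took 9.54% of the WT and 11.7% of the IL31RAKO cells. This left 10795 WT and 12909 IL31RAKO cells, 23704 in all, with medians of 2829 and 2980 UMIs and 1200 and 1216 genes per cell.

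Counts were scaled to 10000 per cell and log-transformed, and the 2000 most variable genes, 30 principal components and 15 exact nearest neighbours gave 24 clusters by the Leiden method at resolution 1.0, with both libraries clustered together and not integrated. Clusters were ranked for leading genes with a pseudocount of 20 CPM (UMI counts scaled to a fixed total for each library). Clusters were named from 27 lists of marker genes, with "-like" marking such a name. The Cd7/Avil, Gzmc/Xcl1, Apod/Rbp4 and Retnla/Fn1 clusters were set apart by their marker scores but named by leading genes instead of a cell type. The Retnla/Fn1 cluster was the one that passed no score limit. The cluster of mast cells and basophils was split again at resolution 0.5 with 500 variable genes and 10 components. The T-like clusters 0, 1 and 12 were compared by number, because the leading genes of clusters 0 and 1 included more markers of other lists than of the T cell list. The 10 leading genes of cluster 1 held 3 markers of type 2 innate lymphoid cells (ILC2), 2 of CD8 T cells, 1 of dermal gamma-delta T cells and 0 of the general T cell list, although the T cell list had its highest score.

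No statistical test was possible with 1 library per group, and cells were not treated as replicates, so there are no p-values. Shares of cells are given with exact binomial (Clopper-Pearson) 95% intervals. Gene levels are CPM of the UMIs summed over a class of cells, and ratios are IL31RAKO over WT with exact 95% counting intervals, given in brackets. All intervals cover counting error only and hold no variation between mice, pools or sorts. Those of gene ratios also hold no variation between cells, so they are too narrow where few cells hold most UMIs. The UMIs held by 1 cell are printed for some genes only, so their absence does not mean that a gene was spread over many cells. For a gene with 0 counts on a side, the bound of its exact counting interval nearest to 1 is given (at least), computed from the observed 0. A floor of 3 counts in that class replaced the 0 in the ratio itself, not in that bound. Genes were compared in the 16 classes with 100 or more cells in each library. The genes named were those whose interval bound nearest to 1 lay farthest from 1, among genes with 50 or more UMIs in the class: 10 higher and 10 lower in the most numerous T-like class (cluster 1) and the most numerous myeloid class (macrophage-like), and 3 and 3 in the others, of which not every gene is printed. Mitochondrial, ribosomal, haemoglobin, antigen receptor, sex-linked and unnamed genes were left out of that ranking, as were genes that, in the library where they were higher, lay below their level in that library's barcodes of 10 to 50 UMIs, which hold free RNA rather than cells. A named gene can thus lie below free RNA in the other library. Members of the 20 fixed gene lists were named in addition.

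The lists covered type 2 cytokines and regulators, type 17 cytokines and regulators, type 1 and cytotoxic genes, regulatory T genes, T cell activation, naive and memory recirculation, proliferation, alternative macrophage activation, inflammatory myeloid cytokines, interferon response, MHC class II presentation, leukocyte chemokines, the IL-31 receptor pathway, neuropeptide and neurotransmitter receptors, cAMP-responsive genes, STAT6 target genes, dissociation and stress genes, mast cell and basophil effector genes, glycolysis and hypoxia, and sex-linked genes. The median log2 ratio of a list's members with 20 or more UMIs was set among 10000 random lists of the same size matched on mean expression in 20 bins. Its percentile describes these libraries only. Shares of T-like cells with a UMI of a cytokine were compared after each cell was thinned at random to 1000 UMIs, with shallower cells left out.

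The ratio and interval step was tested on simulated counts for T-like cluster 1 (8252 genes, 200 of them changed). There 95.9% of intervals held the true ratio, and 4.10% of unchanged genes had an interval excluding 1. Of genes changed 1.5-fold 83.7%, and of genes changed 2-fold 96.9%, had an interval excluding 1 in the right direction. The simulated counts followed the counting model that the intervals assume, with no variation between cells. The simulation thus checks the calculation and not how well the intervals suit the real counts.

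The filters, the clustering settings, the marker and gene lists, the naming rule for genes and the following other settings were fixed before the data were examined: a minimum of 1000 UMIs, a minimum per library from an order-of-magnitude rule (1/10 of the 99th percentile of the 3000 deepest barcodes, 2042 UMIs in WT and 2373 in IL31RAKO), a mitochondrial limit of 5%, no doublet removal, resolutions of 0.5 and 2.0, another seed, scoring of each cell by marker lists, another denominator, median-of-ratios scaling, a mean over cells, a total without mitochondrial, ribosomal and haemoglobin genes, subtraction of free RNA, other member minimums of 5 and 50 UMIs, and thinning to 500 or 2000 UMIs or not at all. Other choices followed a look at the data. The score limits used in naming clusters were set while looking at the clusters. The T-like clusters were at first compared as 1 class and split by number after those values had been seen. Of 357 combinations of class and list, 38 were carried into the alternatives and 8 of those lead the comparisons, picked after the medians had been seen. Clustering without the 3554 genes that differed 1.5-fold or more within a class (19 clusters), a free-RNA profile from barcodes of 50 to 200 UMIs, each macrophage-like cluster alone, leaving out the deepest-counting cell of a gene, and a denominator without neutrophil-like and monocyte-like cells were added as further settings.

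The work used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, scikit-image 0.26.0 and matplotlib 3.10.9. Gene coordinates are those of mm10, from an annotation of that build matched on Ensembl gene identifiers. T cell receptor sequences, sequencing reads and deletion breakpoints were not analysed here.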

Results

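Leukocytes of inflamed skin were compared between mice with and without the receptor for IL-31, a cytokine of T cells known for causing itch. House dust mite ointment had been applied to the shaved dorsal skin 2 times a week for 3 weeks, each time after a 2% SDS wash. Each group was 1 library of sorted live CD45+ cells pooled from 4 mice, so there were no replicates, and every difference below is between 2 libraries. The WT library held 57000499 UMIs and the IL31RAKO library 71333292. The 10795 WT and 12909 IL31RAKO cells kept had medians of 2829 and 2980 UMIs. Ratios are IL31RAKO over WT, and brackets hold 95% intervals that cover counting error only.

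The targeted gene, Il31ra (ENSMUSG00000050377, mm10 chromosome 13, 112519898 to 112594360), was close to the limit of detection in both libraries. It had 10 UMIs in WT (exact Poisson interval 4.80 to 18.4; 0.251 CPM) and 24 in IL31RAKO (15.4 to 35.7; 0.479 CPM). A 3′ tag can lie outside the deleted part of a gene, so these counts check nothing about the deletion or the labels. The ligand gene Il31 had 0 UMIs in both libraries, which allows up to 0.0278% of WT and 0.0232% of IL31RAKO cells with a UMI. Osmr, the partner chain of the IL-31 receptor, had 61 and 49 UMIs, and Il6st, the gp130 chain shared by cytokines of the IL-6 family, had 1334 and 1420. Xist, the female-specific RNA, had 0 UMIs in both libraries, and the Y-linked Ddx3y had 2413 and 2782.

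The comparison of cell classes asked how the make-up of the leukocyte infiltrate differed without the IL-31 receptor. Neutrophil-like, monocyte-like and macrophage-like cells held larger shares of the IL31RAKO library. Dermal gamma-delta T-like cells, Langerhans-like cells and the Cd7/Avil cluster, whose leading genes include Cd3e, Cd3g and Nkg7, held smaller ones. Regulatory T-like cells held a larger share beside a smaller share of the other T-like clusters.

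Neutrophil-like cells, led by the calprotectin genes S100a8 and S100a9, made up 2.69% of WT cells (290 cells, 2.39 to 3.01%) and 9.06% of IL31RAKO cells (1169 cells, 8.57 to 9.56%), a ratio of 3.37 [2.96, 3.85]. Monocyte-like cells were at 4.05% and 7.95% (1.96 [1.75, 2.20]) and macrophage-like cells at 15.7% and 22.4% (1.42 [1.34, 1.51]). The macrophage-like ratio was 1.63 in cluster 9, led by Ccl8, Pf4 and Cbr2, and 1.12 in cluster 10, led by Sgk1, Cxcl16 and Thbs1. Dendritic cells resembling the cross-presenting type 1 (cDC1-like) were at 1.44% and 2.24% (1.56 [1.28, 1.91]). Those resembling type 2 (cDC2-like) were at 8.73% and 7.44% (0.853 [0.779, 0.934]), and that direction reversed under 3 of the other settings. The Apod/Rbp4 cluster had a ratio of 1.27 [1.07, 1.51] and the Retnla/Fn1 cluster one of 1.09 [0.971, 1.23]. Basophil-like cells (95 and 140), mast-like cells (4 and 11) and B-like cells (13 and 27) had intervals that included 1.

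Dermal gamma-delta T-like cells, marked by Blk, Cd163l1 and Il17a, were 8.54% of WT cells (922 cells, 8.02 to 9.08%) and 3.21% of IL31RAKO cells (414 cells, 2.91 to 3.53%), a ratio of 0.375 [0.334, 0.422]. Langerhans-like cells, the antigen-presenting cells of the epidermis, were at 2.36% and 1.06% (0.449 [0.362, 0.555]). The Cd7/Avil cluster was at 6.88% and 3.41% (0.495 [0.439, 0.558]), and the Gzmc/Xcl1 cluster, which shared markers of epidermal T cells and NK cells, at 1.90% and 0.875% (0.461 [0.363, 0.583]). The T-like clusters together were at 29.0% and 22.7% (0.784 [0.746, 0.825]), with 0.699 in cluster 0, 0.813 in cluster 1 and 0.879 [0.769, 1.01] in cluster 12. Regulatory T-like cells, marked by Foxp3 and Ctla4, were at 5.34% and 7.29% (1.37 [1.23, 1.52]). Cycling lymphoid cells had a ratio of 0.574 [0.479, 0.686], cycling myeloid cells one of 1.13 [0.749, 1.73] and mature DC-like cells one of 0.588 [0.392, 0.874]. Of the cells that a CD45 sort should exclude, keratinocyte-like (92 and 42) and endothelial-like cells (67 and 23) had ratios of 0.382 [0.258, 0.556] and 0.287 [0.171, 0.467], and fibroblast-like cells one of 1.02 [0.690, 1.51].

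The sort and the digest can set these shares in part, which could not be measured here, and some genes leading the clusters themselves differed between the libraries. Clustered without the differing genes, 12 of 13 shares kept their direction. The dermal gamma-delta T-like, monocyte-like, Gzmc/Xcl1 and Retnla/Fn1 cells formed no cluster of their own there, so their shares lack that check. Assigning each cell by its own marker score gave log2 ratios of −1.39 for dermal gamma-delta T-like and 1.04 for monocyte-like cells. Il17a, a marker of the dermal gamma-delta T-like cells, and Chil3, which leads the monocyte-like cluster, themselves differed between the libraries. The score can rest on such genes, so it does not replace that check.

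**Figure D1:**
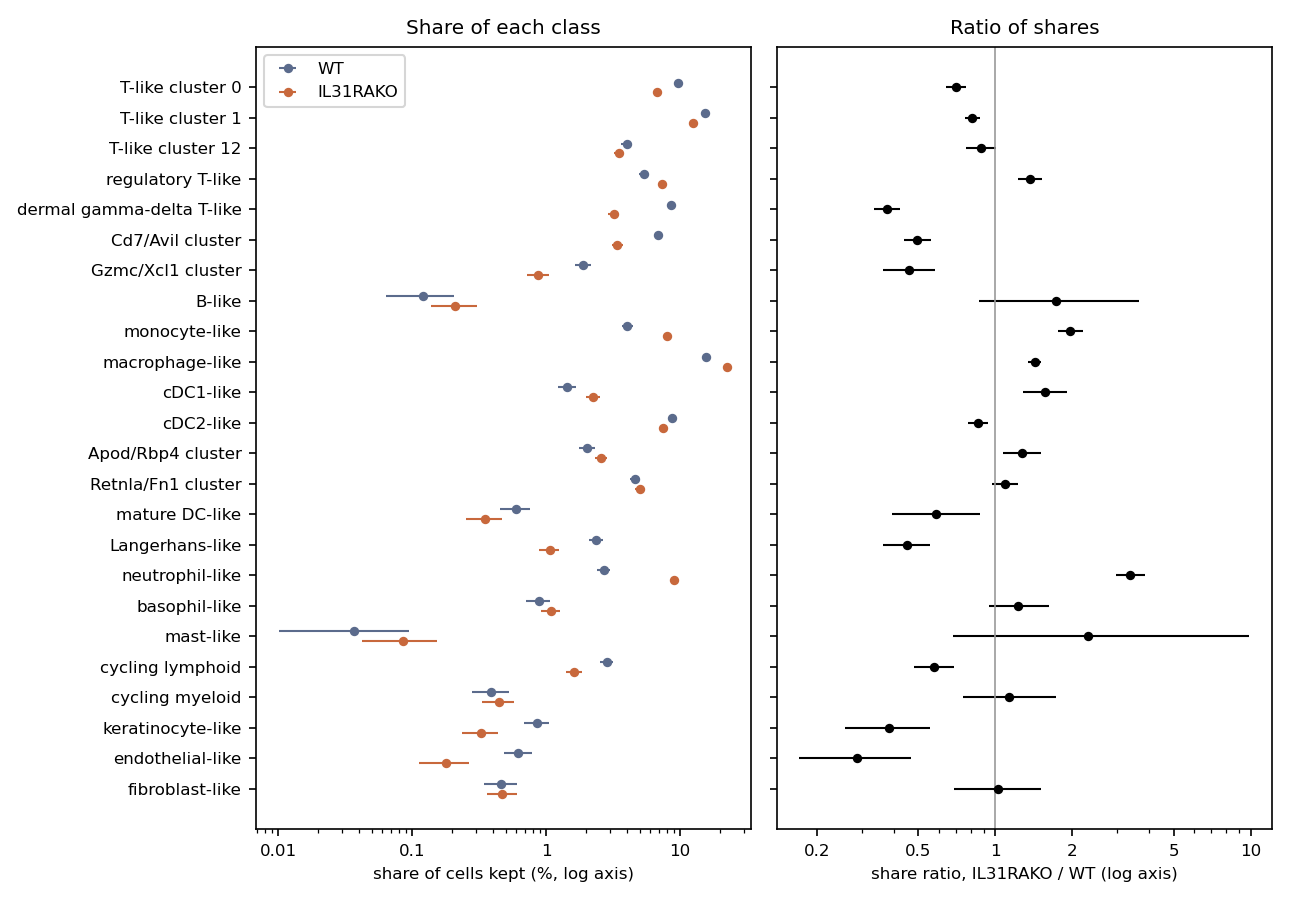
Left, the share of each cell class among the cells kept (percent, log axis) in the WT and IL31RAKO libraries; right, the ratio of the shares (log axis), with bars for exact 95% counting intervals. Neutrophil-like cells lie highest among ratios whose interval excludes 1, at 3.37, and endothelial-like cells lowest, at 0.287.

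The comparison within T-like cluster 1, the most numerous T-like class (1652 WT and 1607 IL31RAKO cells), asked which cytokine and activation programmes differed without the receptor. The type 17 cytokine genes Il17a, Il17f and Il22 were lower in the IL31RAKO library, and Il13, a main cytokine of type 2 inflammation, was higher. For Il4, its partner in type 2 responses, no difference was detectable. The list of glycolysis and hypoxia genes had a higher median. Il13, Areg and Rora, which lead this cluster, are also markers of type 2 innate lymphoid cells, and such cells were not separated from it. The T cell receptor component Cd3d had 6258 and 5936 UMIs in the cluster.

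The type 17 list had a median log2 ratio of −0.28, with 9 of 12 members lower, at percentile 0 of the random lists; the intervals of 5 members lay below 1 and those of 3 above it. Il17f was at 2300.4 CPM in WT and 1622 in IL31RAKO (0.705 [0.685, 0.725]), Il17a had a ratio of 0.773 [0.756, 0.790], and Il22, which acts on keratinocytes, one of 0.802 [0.772, 0.834]. Maf, a regulator of IL-17-producing T cells, was at 0.704 [0.656, 0.755], while Ahr was at 1.43 [1.16, 1.76]. These cytokines were among the genes leading this cluster, so the cells were in part grouped by them. The type 2 list had a median of 0.15, with 8 of 13 members higher, at percentile 98.8. The intervals of 5 members lay above 1 and those of 2 below it, among the latter Areg at 0.699 [0.675, 0.723]. Il13 went from 1024 to 1478 UMIs (1.35 [1.25, 1.46]), Il17rb, a receptor chain for IL-25, had a ratio of 1.77 [1.09, 2.93] and the chemokine receptor gene Ccr8 one of 1.36 [1.13, 1.65]. Il4 had 30 and 28 UMIs (0.873 [0.503, 1.51]) and Il5 a ratio of 0.985 [0.616, 1.58], so no difference was detectable at this depth. Il10, which encodes an inhibitory cytokine, had a ratio of 1.72 [1.40, 2.13].

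The regulatory T list had a median of 0.59 in cluster 1, with 10 of 14 members higher, at percentile 100. Foxp3, Ikzf2, Klrg1 and Gzmb among those members lay below their level in free RNA, so Foxp3 is not read as expressed by these cells. With free RNA subtracted the median was 0.68. The costimulatory receptor gene Tnfrsf9 (4-1BB) went from 241 to 538 UMIs (2.09 [1.79, 2.44]), Tnfrsf4 (OX40) from 667 to 1339 (1.88 [1.71, 2.06]) and Tnfrsf18 (GITR) had a ratio of 1.48 [1.36, 1.61]. In WT, Tnfrsf9 (49.0 CPM) and Tnfrsf4 (136) lay below their free-RNA levels of 63.7 and 161 CPM, and Tnfrsf4 in IL31RAKO (255) was close to its level of 247, so free RNA can hold a part of both differences. The glycolysis and hypoxia list had a median of 0.35 with 13 of 13 members higher, 11 of them with an interval above 1, at percentile 100, among them Gapdh (1.38), Pkm (1.31) and Ldha (1.19). Other genes named by the fixed rule as higher were Zfp36l2, an RNA-binding protein that destabilises transcripts (1.71), Zeb1, a transcriptional repressor (2.02), Wee1, a kinase that holds back mitosis (3.02), Mxd1, a MYC antagonist (1.79), the receptor gene Cd160 (1.95), Atp6v0c (2.18) and Wdfy1 (2.35). Cxcl3 was also named (2.78), but 30 of its 98 IL31RAKO UMIs came from 1 cell. The lower genes were led by the peptide transporter Slc15a2 (0.244 [0.118, 0.468]) and by St8sia1, which makes the ganglioside GD3 (0.380). They also included B3galt2 (0.386), Xlr3b (0.406), the potassium channel gene Kcnc1 (0.480), Mturn (0.537), Selm (0.567), Fam177a (0.630) and Areg, which encodes the EGF receptor ligand amphiregulin (0.699 [0.675, 0.723]).

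Of the other lists in cluster 1, the type 1 and cytotoxic list had a median of −0.01 (percentile 50.9), T cell activation 0.06 (93), naive and memory recirculation 0.11 (95.8), proliferation 0.10 (98.1), the IL-31 receptor pathway 0.04 (78.3) and the cAMP-responsive genes −0.04 (19.3). Neuropeptide and neurotransmitter receptors had a median of 0.22 (96.6), from 5 members measured. The STAT6 target list was at 0.37 (100), but it shares macrophage genes such as Chil3 and Retnla with the free RNA. The inflammatory myeloid list (0.78) and the leukocyte chemokine list (0.48) were higher too. Most of their members, Il1b and Ccl8 among them, lay below their level in free RNA in this cluster.

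The share of cells with a UMI gave the same directions over the T-like clusters together, whose median depths were 2522 and 2678 UMIs. After thinning to 1000 UMIs, which left out 385 WT and 297 IL31RAKO cells, Il13 was found in 7.62% and 11.6% of cells (1.53 [1.28, 1.83]; 15% and 21.7% unthinned). In macrophage-like cells, which should lack Il13 and had median depths of 2240.5 and 2904 UMIs, the share was 0.216% and 0.594%. Il17a was found in 50.5% and 39.3% of T-like cells (0.779 [0.718, 0.845]; 61.6% and 51.9% unthinned) against 8.66% and 5.67% of macrophage-like cells. Il22 was found in 17.3% and 12.5% (0.722 [0.625, 0.833]; 23.9% and 18.1% unthinned) against 1.66% and 1.51%. Il4 was found in 19 and 12 cells, but in 17 and 26 after thinning to 2000 UMIs and in 34 and 38 unthinned, so no direction is read for it. The background share of Il17a was thus also lower in the IL31RAKO library. That of Il13 was higher, with a CPM ratio in macrophage-like cells of 2.01 [1.18, 3.60], so background can hold a part of both differences.

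Other classes shared parts of this pattern, among them classes that should lack these cytokines. Regulatory T-like cells did not share its type 17 part. Il17a had a ratio of 1.497 [1.286, 1.747] there, although it lay below its free-RNA level in both libraries. The type 17 list was at 0.154 (percentile 97.04) in these cells, with a counting interval that included 0. The type 2 and type 17 lists were at 0.30 (percentile 99.1) and −0.23 (1.46) in macrophage-like cells, with counting intervals that included 0, and at 0.27 (99.5) and −0.22 (3.92) in cDC2-like cells. The type 17 list was at −0.45 (0.06) in the Retnla/Fn1 cluster, so the shifts of these lists are not particular to T cells. In T-like cluster 0, led by Cd8b1 and Cd8a, the type 2 list had a median of 0.33 (percentile 99.9), the type 17 list −0.29 (0.02) and the glycolysis list 0.29 (100), with Il13 at 1.59 [1.29, 1.97] and Il17a at 0.613 [0.570, 0.658]. In T-like cluster 12, led by Ifng and Ccl5, the type 17 list was at −0.33 (0.38), the type 2 list at −0.12 (20.5) and T cell activation at −0.27 (0.11), beside a stress list at −0.38 (0) with 16 of 18 members lower. There Gzmk, a granzyme of memory-type CD8 T cells, had a ratio of 7.32 [3.91, 15.2], Ifitm1 4.58 and Ly6c2 2.96. Cd40lg, the helper ligand for CD40, was at 0.404 [0.337, 0.482] in this cluster, Xcl1 at 0.270 and Hspa1a at 0.181. Of the Xcl1 UMIs, 83 of 269 in WT and 32 of 83 in IL31RAKO came from 1 cell. In cluster 0 the rule named Acta1, at least 30.2-fold higher but with 81 of its 107 UMIs in 1 cell and reversed to a log2 ratio of −1.66 without doublet removal, Mylpf (11.5; 34 of 54 UMIs in 1 cell) and Ms4a4a (4.45), and as lower Ccl1 (0.0673; 51 of 63 WT UMIs in 1 cell), the acid-sensing channel gene Asic3 (0.177) and Hspa1b (0.354).

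Regulatory T-like cells (576 and 941) had a regulatory T list median of 0.18, with 11 of 14 members higher (percentile 99.8), and a proliferation median of −0.22 (0.09). Ctla4, an inhibitory receptor, was at 1.27 [1.18, 1.36] and Foxp3 at 1.14 [0.998, 1.31]. Ltf (2.28, with 21 of 67 WT UMIs in 1 cell) and Rln3 (2.60) were higher. So was Gzma, whose 289 IL31RAKO UMIs came from 19 cells with 99 in 1 of them. Hspa1a (0.309), Syce2 (0.368) and Cdk2ap1 (0.468) were lower. Cycling lymphoid cells formed a class of their own, so the proliferation list in the other lymphoid classes covers only cells outside it. In dermal gamma-delta T-like cells the proliferation list was at −0.43, with 21 of 22 members lower (percentile 0). Areg was at 1741 and 587 CPM there (0.337 [0.313, 0.363]), Il17a was at 0.648 [0.621, 0.676] and Il17f at 0.594 [0.556, 0.634], although the type 17 list as a whole was at −0.01 (69.6) and the type 2 list at 0.21 (97.3). Nrp1 (3.75), Vill (3.68) and Ifngr1, the receptor for interferon gamma (2.40), were higher in these cells, and Neb (0.110 [0.0221, 0.335]) and Hsd17b13 (0.149) lower. In WT, Nrp1 (8.96 CPM), Vill (6.36) and Ifngr1 (107) lay below their free-RNA levels of 25.5, 12.7 and 293 CPM.

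In the Cd7/Avil cluster, Dynlt1f (3.04), Ramp3, a subunit of calcitonin-family receptors (1.88), and Sh3bgrl2 (2.54) were higher and Cmc4 (0.301), Ptpn9 (0.350) and Areg (0.552) lower. In the Gzmc/Xcl1 cluster, the cytotoxic granule genes Gzmb (4.20), which was higher in every class compared, and Gzma (2.97) and the chemokine gene Ccl4 (2.98) were higher. Of the 424 IL31RAKO UMIs of Ccl4, 103 came from 1 cell, and its WT level (285 CPM) lay below that of free RNA (782). Lower in this cluster were Ccl1 (0.0381, with 285 of 838 WT UMIs in 1 cell), the inhibitory receptor gene Lag3 (0.388) and Hspa1b (0.319). In cycling lymphoid cells, the opioid precursor gene Penk (12.6; 82 of 215 UMIs in 1 cell), Gzmb (4.59) and Tnfsf8 (4.21) were higher. The pigment cell genes Dct, Pmel and Mlana were at least 89.1-fold, 49.0-fold and 22.6-fold lower there, with 443, 243 and 114 UMIs from 1 WT cell.

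**Figure D2:**
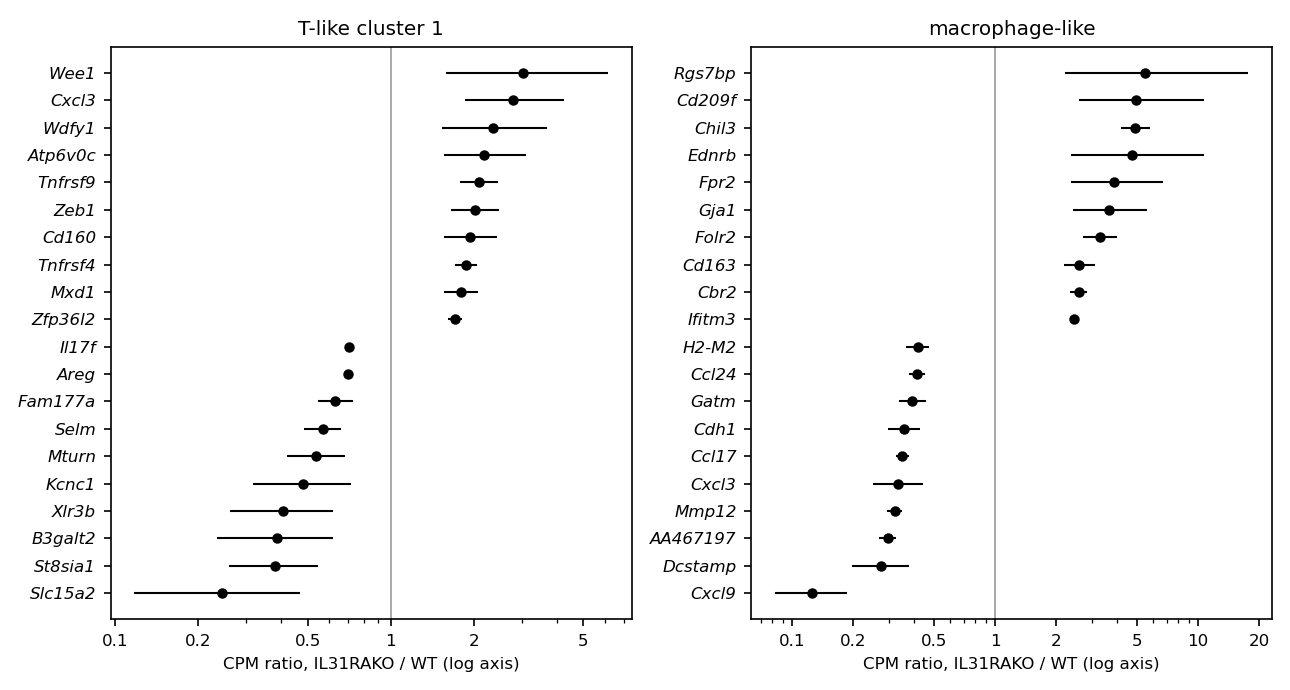
CPM ratio of the genes named by the fixed rule (IL31RAKO over WT, log axis) in T-like cluster 1 and in macrophage-like cells, with bars for exact 95% counting intervals. In T-like cluster 1 Slc15a2 lies lowest at 0.244, and in macrophage-like cells Cxcl9 lies lowest at 0.126.

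The comparison within macrophage-like cells (1696 and 2890), the most numerous myeloid class, asked whether their state differed along with their number. The scavenger receptor gene Cd163, the folate receptor gene Folr2 and Cbr2 were among the genes higher in the IL31RAKO library. Interferon-response genes were higher as a list, but the interferon-induced chemokine gene Cxcl9 was lower. The T cell-attracting chemokine gene Ccl17 and Mmp12, the macrophage elastase, were lower. Many of these differences were smaller within clusters 9 and 10, and the differing mix of these clusters held a part of some of them.

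Chil3, which encodes the chitinase-like protein Ym1, went from 34.1 to 167 CPM (4.91 [4.19, 5.80]), but its WT level lay below that of free RNA (132 CPM) and it was higher in 15 of 15 classes measured, T cells included. Folr2 went from 26.6 to 87.4 (3.28 [2.73, 3.98]), Cd163 from 32.9 to 85.5 (2.60 [2.20, 3.1]) and Cbr2 from 102 to 265 (2.59 [2.35, 2.85]). Mrc1, the mannose receptor, had a ratio of 1.57, Ccl8 2.02 and Ccl6 2.06. The rule also named Ednrb, an endothelin receptor (4.74), Fpr2, a formyl peptide receptor (3.87), the connexin gene Gja1 (3.63), Cd209f (4.97; 18 of 92 UMIs in 1 cell), Rgs7bp (5.51) and the antiviral gene Ifitm3 (2.46 [2.34, 2.59]). Cxcl9 had 133 and 31 UMIs (0.126 [0.0823, 0.187]), in 30 and 14 cells. Mmp12 was at 0.321 [0.295, 0.349], AA467197 at 0.296, Dcstamp, a gene of cell fusion, at 0.275, the E-cadherin gene Cdh1 at 0.357, Gatm at 0.392 and H2-M2 at 0.417. Ccl17 was at 0.350, with 461 of its 1115 IL31RAKO UMIs in 1 cell. Ccl24 was at 0.411, and higher in cluster 9 alone (log2 ratio 0.46). Cxcl3 was at 0.333, with 110 of 133 WT UMIs in 1 cell, and reversed to a log2 ratio of 0.67 without the deepest-counting cells.

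Within the clusters of the macrophage-like class most of these differences kept their direction but many were smaller. In cluster 9 alone, 11 of 18 named genes moved beyond their counting interval and 1 reversed, and in cluster 10 alone 8 of 16 moved. The log2 ratio over the class was 1.38 for Cd163, against 1.02 in cluster 9 and 0.38 in cluster 10, and 1.37 for Cbr2, against 0.95 and 1.45. For Folr2 it was 1.72 over the class and 1.26 in cluster 9. Mmp12 was at −1.64 over the class and at −0.63 and −1.29 in the clusters, and Ccl17 at −1.51 against −0.48 and −0.99. For Cd163, Mmp12 and Ccl17 the value over the class lay outside the range of both clusters. A part of these differences thus came from the mix of the clusters, whose share ratios were 1.63 for cluster 9 and 1.12 for cluster 10. Ifitm3 was at 1.30 over the class and at 1.26 and 1.27 within it.

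The interferon list had a median of 0.40 with 14 of 17 members higher (percentile 100), Isg15 being at 1.46 [1.25, 1.72] and Ifi27l2a at 1.39 [1.33, 1.45]; Cxcl9, Cxcl10 and Gbp2 were the members that were lower. Its median was 0.39 in cluster 9 alone and 0.12 in cluster 10 alone. The alternative activation list, which holds genes induced by IL-4 and IL-13, had a median of −0.09 (2.0). Chil3, Mrc1 and Ccl8 were on its higher side and Ccl17, Ccl24 and Ccl22 on the lower. The sign of this median was not stable. It was 0.31 in cluster 9 alone, 0.01 in cluster 10 alone, 0.16 with a minimum of 1000 UMIs and 0.22 without doublet removal. Leukocyte chemokines were at −0.31 (percentile 0) and inflammatory cytokines at −0.22 (0.01), both with 14 members lower, but without doublet removal chemokines were at −0.0600 and inflammatory cytokines reversed to 0.0385. Within clusters 9 and 10 these medians were −0.02 and −0.11 for chemokines and −0.02 and −0.04 for inflammatory cytokines. Proliferation was at −0.43 (0), with −0.0938 in cluster 9 and −0.57 in cluster 10. Cycling myeloid cells formed a class of their own, so this list in the other myeloid classes covers only cells outside it. Glycolysis was at −0.19 (0.155), with a reversed 0.0600 in cluster 9 and −0.12 in cluster 10. The stress genes were at −0.17 (0), with −0.39 in cluster 9 and a reversed 0.0473 in cluster 10. MHC class II was at −0.14 (1.83), with −0.10 in cluster 9 and −0.04 in cluster 10. The STAT6 targets were at −0.06 (10.2) over the class, but at 0.31 in cluster 9 alone and 0.10 in cluster 10 alone.

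**Figure D3:**
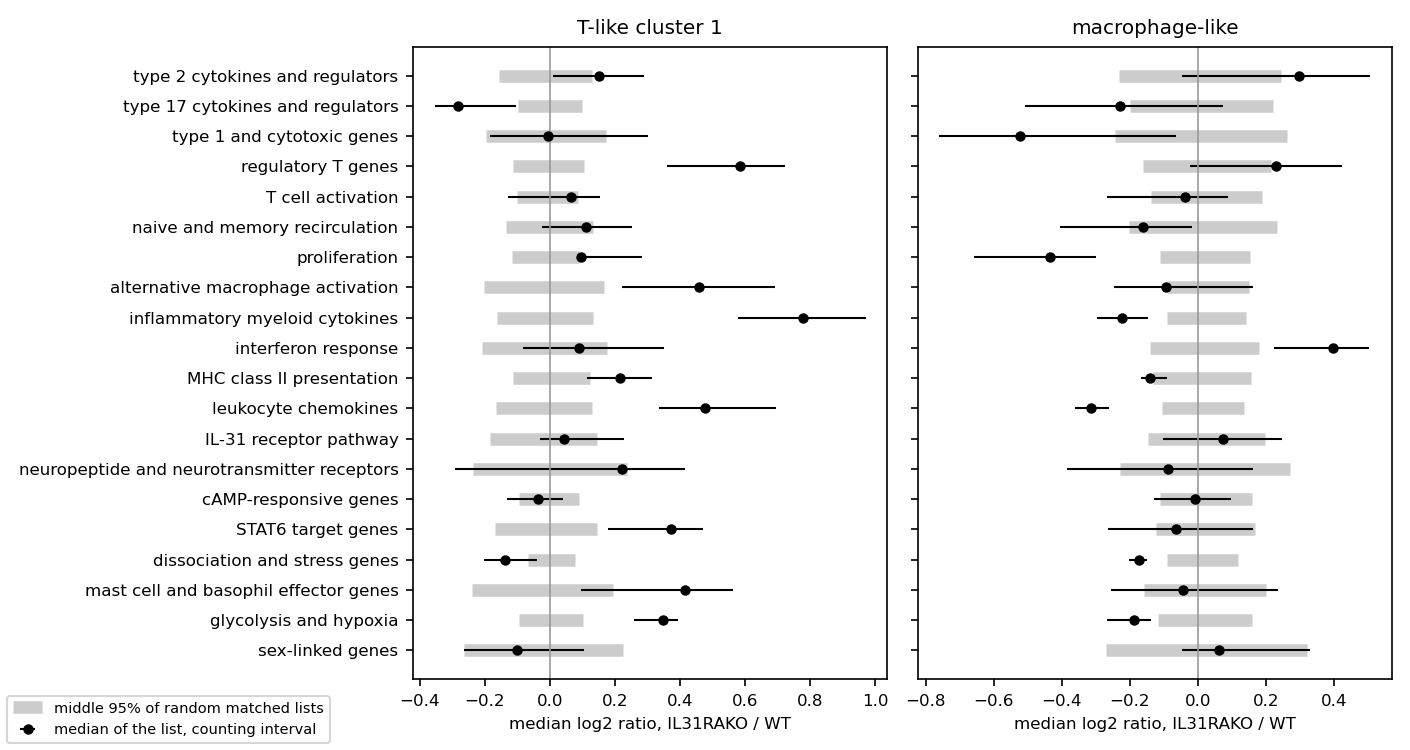
Median log2 ratio (IL31RAKO over WT) of the 20 gene lists in T-like cluster 1 and macrophage-like cells; points with bars are medians with counting intervals, and grey bands hold the middle 95% of 10000 random matched lists. In T-like cluster 1, type 17 cytokines lie at −0.28 and glycolysis at 0.35.

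The other myeloid classes were compared for the same question. Monocyte-like cells had more RNA of inflammatory genes, among them Il1b, and of the monocyte-attracting chemokine genes Ccl7 and Ccl12. Neutrophil-like cells had more of the chemokine gene Cxcl3.

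In monocyte-like cells the inflammatory list was at 0.36, with 11 of 16 members higher (percentile 100), Il1b at 1.38 [1.31, 1.45] and Cxcl2, which attracts neutrophils, at 1.58 [1.47, 1.69]. The neutrophil gene S100a8 went from 40.9 to 157 CPM in these cells, below its level in free RNA, and Cxcl2 is also among the genes leading the neutrophil-like cluster, so neutrophil RNA can hold a part of these differences. Ccl12 (4.05), Ccl7 (3.08) and C2cd2l (6.14 [1.98, 30.8]) were higher and Ace, the angiotensin-converting enzyme (0.323), Klf2, a transcription factor of quiescence (0.486), and Hspa1b (0.346) lower. In neutrophil-like cells Retnlg (2.37 [2.11, 2.68]), Cxcl3 (2.31 [1.98, 2.72]) and Stx11 (3.18) were higher, and Ltc4s, the leukotriene C4 synthase (0.0793), and Bcl2a1a (0.369) lower. In cDC2-like cells Ifitm6 (3.61), Dynlt1b (3.15) and Ifitm1 (2.31) were higher. Lower in cDC2-like cells were Cox6a2 (0.363, from 8 WT and 9 IL31RAKO cells), H2-M2 (0.526) and Klf2 (0.574). Their MHC class II list was at 0.09 (97.8) and their STAT6 target list at 0.40 (100). In cDC1-like cells Ifitm2 (2.30), Ms4a4a (12.1 [3.18, 102]) and Acta1 (at least 12.1-fold, 99 of 100 UMIs in 1 cell) were higher. Ccl22 (0.147, with 55 of 62 WT UMIs in 1 cell) and Hist1h2ae (0.351, with 28 of 64 IL31RAKO UMIs in 1 cell) were lower.

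In Langerhans-like cells the phospholipase gene Pla2g5 (9.34 [5.27, 17.8]), Timd4 (24.8 [8.01, 125]; 21 of 49 UMIs in 1 cell) and Apol7c (8.95; 49 of 53 in 1 cell) were higher, and Hspa1a (0.238) and the histone genes Hist1h2ae (0.287) and Hist1h2ap (0.354) lower, although the proliferation list was at 0.30 with 17 of 22 members higher (percentile 100). Without doublet removal Apol7c reversed to a log2 ratio of −0.80 and Hist1h2ap to 0.0366. In the Retnla/Fn1 cluster, Retnla, a gene of type 2-activated macrophages (1.73 [1.68, 1.77]), Ccl17 (2.48; 196 of 873 UMIs in 1 cell) and Gpnmb (31.6 [5.41, 1273]; 42 of 49 in 1 cell) were higher and Klf2 (0.499), Hspa1b (0.474) and Hspa1a (0.516) lower. Ccl17 there reversed to a log2 ratio of −0.76 without doublet removal. In the Apod/Rbp4 cluster Bambi (4.34), Scoc (2.80) and Casp6 (1.45) were higher and Hspa1b (0.386), Rasgrp2 (0.408) and Hspa1a (0.588) lower. Over all cells the mast cell and basophil list was at 0.21 (100), with 13 of 18 members higher, and the sex-linked list at −0.14 (34.9). These sums mix all classes, whose shares differed. The mast cell and basophil list also holds genes of other cells, such as Osm, higher in all 16 classes, so nothing about mast cells or basophils is read from it.

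Some genes differed in the same direction in nearly all classes, and these were picked out after their values were seen. Hspa1a, a heat shock gene that responds to handling, was lower in 16 of 16 classes with ratios from 0.181 to 0.815, and Hspa1b in 15 of 16. The stress list was at −0.14 (0.01) in T-like cluster 1, −0.29 (0) in both the Retnla/Fn1 and the Gzmc/Xcl1 cluster, −0.27 (0) in Langerhans-like, −0.25 (2.31) in neutrophil-like and −0.14 (0) in monocyte-like cells, but at 0.12 (99.5) in dermal gamma-delta T-like and at 0.10 (98.4) in cycling lymphoid cells. Ifitm3 was higher in 16 of 16 classes (median ratio 1.94), as was S100a8, a neutrophil gene that T cells should lack. Ifitm1, Ifitm2, Tnfrsf9, Gzmb (median ratio 2.79) and the macrophage genes Ccl8, Ccl6 and Mrc1 were likewise higher in 16 of 16 classes and Xcl1 lower in 16, Chil3 and Ms4a4a were higher in 15 of 15 and Vill in 13 of 13. Of the other genes named, Mxd1 was higher in 16 of 16, Retnla in 15 of 16, Wdfy1 in 13 of 14, Cbr2 in 10 of 10, and Dynlt1b and Ccl12 in 8 of 8 classes. Dynlt1f and Casp6 were higher in 14 of 16, and Ifngr1, Atp6v0c, Zeb1 and Tnfrsf4 in 13 of 16. Fam177a and Cdk2ap1 were lower in 16 of 16, Il17f in 15 of 16 and Xlr3b in 8 of 8. The differences of these named genes are thus not particular to the class in which they were named. Areg was lower in 14 of 16 classes, Il17a in 15 of 16 and Slc15a2 in 8 of 8, and Il13 was higher in 13 of 15, with an interval above 1 in 5. Free RNA was estimated at 8.39% of WT and 12.4% of IL31RAKO UMIs from barcodes of 10 to 50 UMIs, and at 16.4% and 13.4% from those of 50 to 200. It can hold a part of a shared difference such as that of S100a8 (514 and 632 CPM in the free RNA). The free-RNA levels of Hspa1b (59.5 and 31.6), Il17a (624 and 537), Slc15a2 (8.50 and 0), Nnt (4.25 and 15.8) and Dynlt1b (0 and 5.26) also ran the same way as their differences. Those of Hspa1a (119 and 221), Areg (319 and 437), Il13 (63.7 and 36.8), Ifitm3 (718 and 584) and Gzmb (132 and 100) ran the other way. The profiles of 10 to 50 UMIs held only 235401 and 189990 UMIs, however. These levels thus rest on few counts, and free RNA is not excluded as a part of any of these differences.

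**Figure D4:**
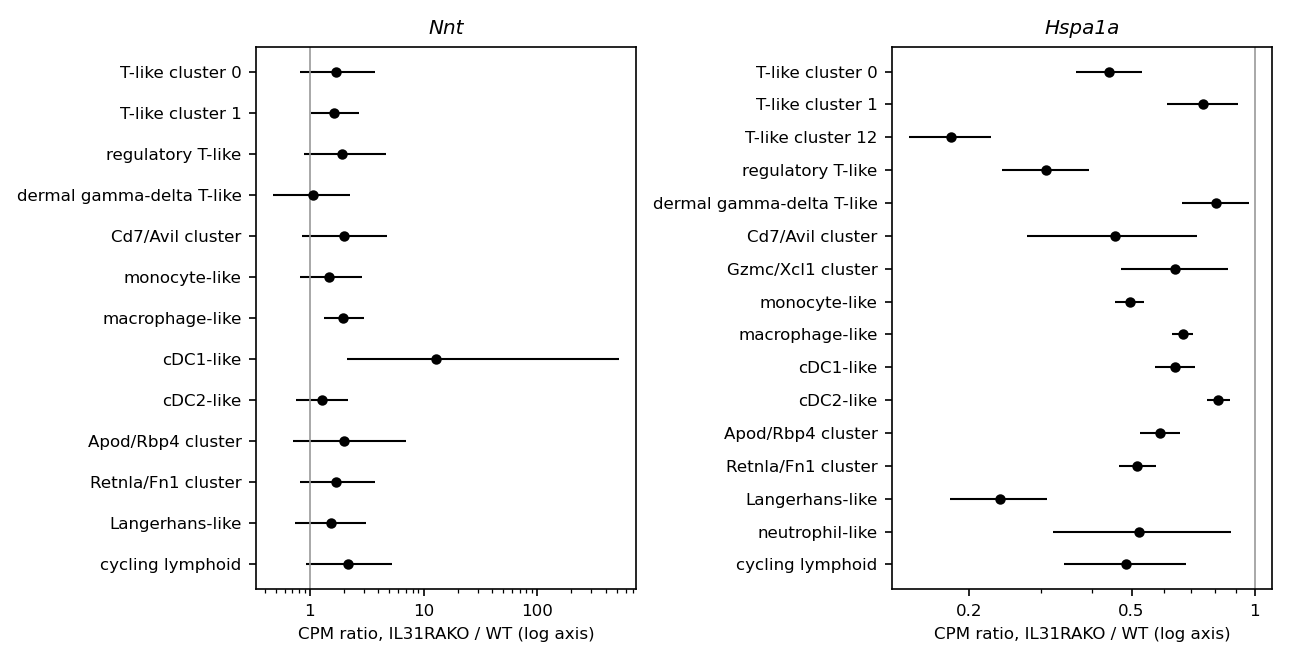
CPM ratio of Nnt and Hspa1a (IL31RAKO over WT, log axis) in each class where they were measured, with bars for exact 95% counting intervals. Nnt lies above 1 in 13 of 13 classes and Hspa1a below 1 in 16 of 16.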

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

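The alternatives without the genes that differ, with each macrophage-like cluster alone, with the free-RNA profile of 50 to 200 UMIs, without the deepest-counting cell and with a denominator lacking neutrophil-like and monocyte-like cells were chosen after the results had been seen. Of 165 alternative values of class shares, 137 stayed within the counting interval, 25 moved beyond it and 3 reversed, meaning that the sign changed where the interval of the value reported excludes 0. For gene lists the numbers were 303, 54 and 3 of 360, for named genes 846, 138 and 8 of 992, and for thinned shares 50, 4 and 0 of 54. Changes of sign where that interval included 0 are not counted as reversed: the sign was kept in 162, 334, 984 and 45 of these values. The cause of each move below was not tested unless one is given. All values are log2 ratios.

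With 1000 UMIs as the minimum, the share of cDC2-like cells was −0.0857, alternative activation in macrophage-like cells 0.16 and Cxcl3 there 0.88 (reversed). The order-of-magnitude minimum, which keeps 7741 WT and 8709 IL31RAKO cells and removes shallow ones, gave −0.49 for T-like cluster 1, −0.44 for the T-like clusters together, 0.29 for regulatory T-like, 0.86 for macrophage-like, 0.14 for cDC2-like (reversed) and 2.05 for neutrophil-like cells. A mitochondrial limit of 5% gave 0.35 for macrophage-like and −0.0574 for cDC2-like cells. Resolution 2.0 gave 0.42 for macrophage-like cells.

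Without doublet removal, T-like cluster 1 was at −0.50, glycolysis there at 0.39, and in macrophage-like cells alternative activation was at 0.22, chemokines at −0.0600, inflammatory cytokines at 0.0385 (reversed) and Cxcl3 at 1.59 (reversed). Acta1 in T-like cluster 0 (−1.66), Apol7c (−0.80) and Hist1h2ap (0.0366) in Langerhans-like cells and Ccl17 in the Retnla/Fn1 cluster (−0.76) reversed as well. Scoring each cell by markers gave 0.89 for macrophage-like, 0.25 for cDC1-like, 0.11 for cDC2-like (reversed) and −0.77 for Langerhans-like cells. Clustering without the differing genes gave −0.40 for T-like cluster 12, −0.51 for the T-like clusters together and 0.0130 for cDC2-like cells (reversed), with no value for dermal gamma-delta T-like, monocyte-like, Gzmc/Xcl1 and Retnla/Fn1 cells. Without neutrophil-like and monocyte-like cells in the denominator, all shares move up by construction, to −0.35 for T-like cluster 0, −0.13 for cluster 1, −0.18 for the T-like clusters together, 0.62 for regulatory T-like, 0.68 for macrophage-like and −0.0609 for cDC2-like cells.

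In macrophage-like cells a mean over cells gave −0.12 for inflammatory cytokines and −0.21 for chemokines, and the profile of 50 to 200 UMIs −0.32 and −0.41. Cluster 9 alone gave −0.0183 for both, 0.31 for alternative activation, and reversed Ccl24 (0.46) and glycolysis (0.0600). Cluster 10 alone gave −0.0385 for inflammatory cytokines, −0.11 for chemokines, 0.12 for interferon response and 0.0473 for stress genes (reversed). Subtracting free RNA gave 0.40 for glycolysis in T-like cluster 1. Without the deepest-counting cell, Cxcl3 in macrophage-like cells was at 0.67 (reversed), since 1 WT cell held most of its UMIs. Thinning to 2000 UMIs gave 0.34 for the share of T-like cells with Il13.

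Depth limits Il31ra, Il31, Il4 and Il5, whose counts are too low to show a difference of moderate size. No paired analysis was possible because each group has 1 library, pooled from 4 mice.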

Other observations

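The tests of residual blood, of dermal gamma-delta T-like cells, of dilution and of the chromosome segment were chosen after the results they bear on had been seen; those of lost neutrophils, of free keratinocyte RNA and of respiratory chain genes had been set out beforehand.

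Neutrophil-like cells were 3.37 times as frequent in the IL31RAKO library. Blood left in the tissue brings B cells, of which there were 0.0231 [0.0152, 0.0336] per neutrophil-like cell, but no blood of these mice was measured, so residual blood stays open. Shallow WT neutrophils lost below the UMI minimum do not account for it, because barcodes of 200 or more UMIs rich in neutrophil genes such as S100a8 and S100a9 had a ratio of 4.46 [3.75, 5.33] per cell kept. That rule found only 44.5% of WT and 62.4% of IL31RAKO neutrophil-like cells, but with the marker share lowered to 1%, chosen after the result, it found 84.8% and 94.2% and the ratio was 3.71 [3.29, 4.19], with 44 and 125 barcodes below 500 UMIs. No biological explanation was tested, and the genotype, a difference between the pools of 4 mice, and survival of these cells through digestion and sorting stay open.

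Langerhans-like cells, keratinocyte-like cells and the Cd7/Avil cluster, whose own best score was for epidermal T cell markers, were all lower in the IL31RAKO library, as was the Gzmc/Xcl1 cluster (0.461), which had a higher score for those markers but was left out of the tests. Dilution by the additional neutrophil-like and monocyte-like cells was too small, since without them the summed share still had a ratio of 0.534 [0.483, 0.590]. Macrophage-like cells, which also held a larger share of the IL31RAKO library, stayed in that denominator, so dilution by them was not covered. A digest with less epidermis may be behind the lower shares. Keratinocyte genes such as Krt5 and Krt14 in barcodes of 10 to 50 UMIs had a ratio of 1.41 [1.02, 1.97] (71 and 81 UMIs). That lies above the bound of 0.8 set beforehand for rejecting this explanation. The bound cannot decide, because a CD45 sort should exclude keratinocytes before capture, although 92 and 42 keratinocyte-like cells remained. Free keratinocyte RNA thus need not follow the tissue digested. A condition that the 3 classes also differ among themselves was added after the result, and the explanation stays open. Dermal gamma-delta T-like cells were lower as well, but their ratio of 0.375 [0.334, 0.422] is the pattern itself and tests nothing about the digest, and as no biological explanation was tested the genotype and a difference between pools stay open.

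Nnt, the mitochondrial transhydrogenase gene (mm10 chromosome 13, 119335448 to 119408997), which is known to be partly deleted in C57BL/6J mice, had 236 WT and 509 IL31RAKO UMIs (1.71 [1.47, 2.01]) and was higher in 13 of 13 classes, though with an interval excluding 1 in 3 of them. In free RNA Nnt was at 4.25 CPM in WT and 15.8 in IL31RAKO. Its IL31RAKO level lay below 15.8 CPM in all 13 classes, at most at 13.9. Free RNA can thus hold a part of the difference, although these free-RNA levels rest on few counts. A general difference in mitochondrial gene expression does not account for the Nnt difference, because nuclear genes of the respiratory chain had a median log2 ratio of −0.0491 against 0.78 for Nnt. A chromosome segment from another strain carried along with the targeted Il31ra may be the source, and of the 39 genes measured within 10 Mb of Il31ra, 5.13% (Nnt, and Dhx29, lower in 14 of 14 classes) kept 1 direction in every class. That share lay at percentile 89.5 of random windows with a minimum of 8 classes, which was set when the test was run, and at 96.3 and 96.8 with minimums of 5 and 12 classes, but without Nnt itself at 62.0, 85.8 and 73.9, so the test decides nothing. A segment with another Nnt allele would differ between the libraries in the same way as the genotype, and the 2 cannot be told apart here.

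Haemoglobin RNA was concentrated in 2 WT cells, which held 11885 of the 12552 haemoglobin UMIs in that library, and no IL31RAKO cell reached 10%.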
